A study of Arabidopsis thaliana with 13 samples.

How the data were processed

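Gene expression was measured in 13 cotyledon samples, 1 array each, at 6 h steps from 0 to 72 h. Per the labels, seedlings were grown in liquid MS medium at 22 °C in continuous light for 6 days, and total RNA was labelled as biotinylated cRNA with an Affymetrix one-cycle kit. The deposited values are on a log scale, read here as log2 from their range. The log base, the background correction, the summary method and the normalization are not given in the sources used here. The submitters' processing notes name GCOS, with no version or role. The number of arrays limits the precision, and no signal over background was given.

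The table held 38408 probe sets. The platform annotation used here gave 1 gene to 16722 of them, several to 759 and none to 20927, and probe sets with several or no genes were not named. Names were updated through gene identifiers to the TAIR10.1 annotation, in which 16574 of the 16722 matched. Of 363 genes in 23 lists fixed before the data were examined, 53 were named and 47 tested, and 6 lists had the 3 measured members that camera needed. PXY, WOX4, BEH3, BES1, VND6, VND7, IRX3, APL, SEOR1, LHCB3, CYCB1;1, ARR5 and DWF4, which the rule for named genes included, were not analysed here. The lists marked as added, and families of genes that share a symbol stem, were written after this coverage was known and before any comparison was computed.

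The tests were fixed before the data were examined, with centring on array medians to be used if these differed by over 0.5, as they did. The 30% of probe sets with the lowest mean were left out. Control probe sets were to be left out too, but nothing in the sources used here marks them. Of several probe sets of a gene, the highest by mean was kept, which left 10982 genes, 1330 of them with a symbol. limma 3.58.1 in R 4.3.3 fitted 1 mean per window over all 13 arrays, with 9 residual degrees of freedom and eBayes with an intensity trend. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a log2 difference of at least 1. The smooth course was an F test of a natural spline of 3 degrees of freedom with a fitted range of at least 1. The rhythm was an F test of cosine and sine of 24 h beside linear and quadratic time over the 12 arrays from 6 h on. Lists were tested with camera.

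The list p-values were adjusted over the 18 tests of the fixed lists, as planned, and over the 153 tests of added lists and families separately. A first run had pooled all 171 tests, and the return to the planned family came after that result was seen. In the pool 34 tests passed, 7 of them of fixed lists, against 9 of the fixed and 27 of the others when adjusted apart.

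Named genes were the 8 largest rises and 8 largest falls per window comparison among called genes whose windows did not overlap, and up to 3 called members of each fixed list with the largest difference. For the course they were the 5 largest ranges among called genes. For the rhythm they were the called clock genes and the 5 largest amplitudes among called genes. Genes named outside this rule are said to be.

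The steps were tested on simulated data with the real genes' means and spread, 200 of 10982 genes being changed. For log2 changes of 1, 2 and 3, the share recovered was 42.5, 98.5 and 99.5% for the middle against the early window, 47, 98 and 100% for the late against the middle window, 30.5, 90.5 and 98.5% for the early window against 0 h and 29.5, 93 and 99% for the smooth course. A change of 1 lies at the threshold itself. For the rhythm, 53.5% was recovered at an amplitude of 0.5 and 93.5% at 1. Unchanged genes called numbered between 2 and 11. With 1 list lowered by 1, camera called it and 1 unchanged list. The simulation drew arrays independently and had no array sets.

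Alternatives were quantile normalization, values as deposited, other filters and floors, the mean of a gene's probe sets, other eBayes settings, array weights, leaving out each array, and other windows, splines and periods. Fits within an array set, a term for the sets and centring on named probe sets were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.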

Results

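Cotyledons of 6-day-old Arabidopsis thaliana seedlings of the accession Col-0 were cultured in a medium that induces vascular cells. The culture system, VISUAL, turns leaf cells into xylem and phloem cells in the dish. Per the labels, the medium held the synthetic auxin 2,4-D at 1.25 mg/L, the cytokinin kinetin at 0.25 mg/L and bikinin at 10 µM. Bikinin inhibits GSK3-like kinases and so switches on brassinosteroid signalling. RNA was sampled every 6 h from 0 to 72 h and each of the 13 samples was hybridised to 1 array, so no time point had a replicate. For the comparisons, neighbouring times were grouped into an early window (6 to 24 h, n = 4 arrays), a middle window (30 to 48 h, n = 4) and a late window (54 to 72 h, n = 4), against the lone 0 h array. The SD of a window therefore holds change within the window as well as array error. The p-values measure only the spread between these arrays. Values are on a log scale taken as log2, the base not being given in the sources used here, and every fold rests on that reading.

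The arrays fell into 2 sets by overall level. The medians of the deposited values lay between 5.15 and 5.35 in the 5 arrays of 0 to 24 h and between 5.82 and 5.99 in the 8 arrays of 30 to 72 h. The sets differed by 0.67 in mean median, and each array was therefore centred on its median. The break falls exactly between the early and the middle window, so array set and time cannot be told apart in that comparison. The early window against 0 h lies within the first set and the late against the middle window within the second.

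**Figure D1:**
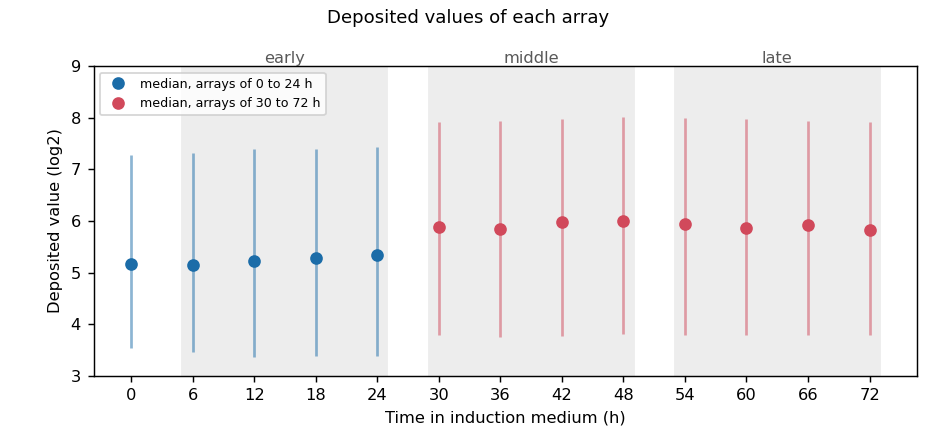
Deposited log2 values of each array against time in induction medium in hours. Points are the median over all 38408 probe sets and lines run from the 25th to the 75th percentile. The 5 arrays of 0 to 24 h have medians of at most 5.35 and the 8 later arrays have medians of at least 5.82.

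The early window against 0 h asked what changed in the first day of culture. Because 0 h is 1 array, it is assumed to vary as arrays within the windows do, and that assumption carries each call of this comparison. Of 6 measured members of the auxin response list, 5 rose and 0 fell, both over all genes and adjusted over the list alone, with a median log2 difference of 1.96. The list passed camera with an adjusted p of 4.53e-05, but with adjusted p = 0.172 with an estimated correlation. Of 3 measured SAUR genes, an added list of auxin-responsive genes, 1 rose, with a median of -0.19 (camera adjusted p = 0.699, and adjusted p = 0.893 with an estimated correlation). GH3.1 and GH3.3, which encode enzymes that conjugate auxin to amino acids, rose 15.1-fold and 9.33-fold. GH3.3 went from 9.47 at 0 h to 12.69 ± 0.08 (SD, n = 4), with an adjusted p of 1.19e-06. IAA30, an Aux/IAA gene, rose 4.79-fold (adjusted p = 0.0213), and the cytokinin response regulator gene ARR15 rose 3.76-fold (adjusted p = 0.0153). Both were dim at 0 h, at 2.52 and 3.71. With values floored at the 40th percentile their log2 differences were 0.18 and 0.57 and neither call held, and that of IAA30 ended at the 20th percentile too, with 1.04. Of 5 measured phloem list members, 2 rose, over all genes and over the list alone. These were CLE44 (8.29-fold, adjusted p = 5.79e-05) and CLE41 (2.76-fold, adjusted p = 0.011), which encode the peptide TDIF that keeps procambial cells dividing and from becoming xylem. BRL1, a brassinosteroid receptor gene of vascular tissue, rose 2.04-fold (adjusted p = 0.0471) as the 1 of 5 measured members of the procambium and cambium list past the test.

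Of 11 measured photosynthesis genes, 3 fell over all genes and 4, SBPASE included, adjusted over the list alone, and 8 did not pass. The median log2 difference was -0.99 (camera adjusted p = 0.0014, and adjusted p = 0.426 with an estimated correlation). LHCB4.2, a light-harvesting protein gene, fell 4.44-fold (adjusted p = 0.00278). PSAN, a photosystem I subunit gene, fell 3.74-fold and PSBW, a photosystem II subunit gene, fell 2.02-fold (adjusted p = 0.0021 and 0.0406). SPCH, the regulator that starts the stomatal lineage, fell 2.11-fold (adjusted p = 0.0419). The sugar transporter gene SAG29, on the senescence list as SWEET15, rose 18.5-fold (adjusted p = 0.0146), while SAG101 of the same list fell 2.14-fold. AUR2, a mitotic kinase gene, rose 3.88-fold (adjusted p = 0.0228), the 1 of 3 measured G2 and M phase genes past the test.

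The largest rises from 0 h were those of AT4G20320 (70.2-fold), AT3G05640 (42.8-fold), the sugar transporter gene SWEET4 (32.7-fold), AT5G52390 (32.4-fold) and WSD1 (31.7-fold), which encodes a wax ester synthase. AT3G60650, AT1G34110 and AT2G47780 followed with rises between 27 and 29.2-fold. The largest falls were those of AT4G27450 (40.9-fold), AT2G38240 (30.7-fold), AT2G45180 (25.6-fold) and AT3G22750 (19.7-fold), followed by AT5G39580, AT1G35350, AT4G22470 and AT2G43140. Their adjusted p lay between 2.21e-07 and 0.0039. In all, 692 of 10982 genes were higher and 603 lower at a Benjamini-Hochberg adjusted p under 0.05 and a log2 difference of at least 1 in limma. Fitted on the 5 arrays of 0 to 24 h alone, the counts were 287 and 157, and the calls of GH3.1, IAA30, ARR15, CLE41, BRL1, AUR2, LHCB4.2, PSAN, PSBW, SPCH, SAG29, AT5G52390, AT2G38240 and AT4G22470 ended. That fit compares the same arrays, so the log2 differences stayed the same and only the spread and its degrees of freedom changed. Several of these calls were lost elsewhere too. Calls ended in 12 of 25 settings for PSBW, 12 of 24 for SPCH and 11 of 25 for BRL1, whose log2 difference was 0.11 with the floor at the 40th percentile (adjusted p = 0.847). The call of AUR2 also ended with 6 and 12 h alone, and that of SAG101 with centring on named probe sets.

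**Figure D2:**
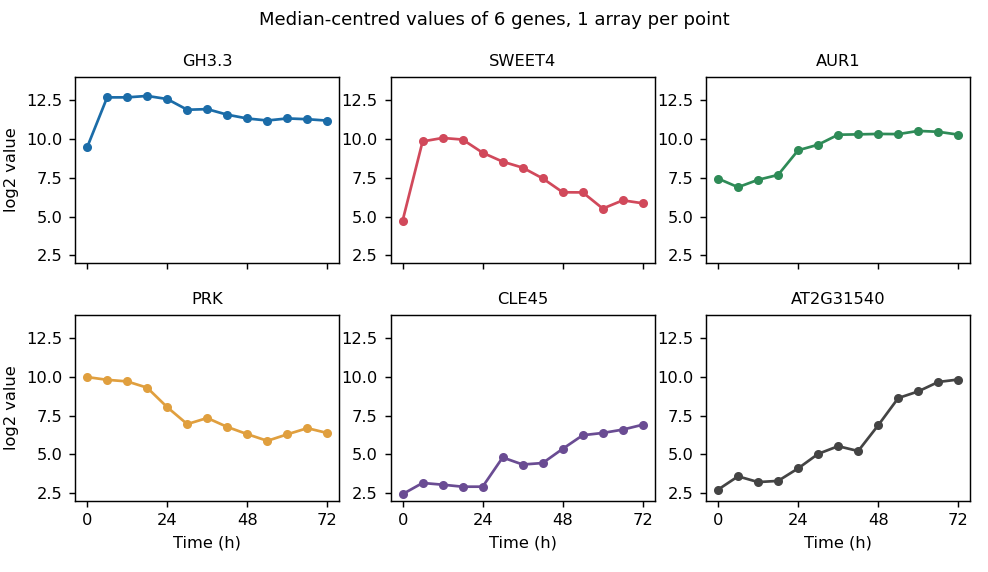
Median-centred log2 values of 6 genes against time in hours, 1 array per point. GH3.3 and SWEET4 were higher from 6 h on, AUR1 rose from 7.69 at 18 h to 9.28 at 24 h, PRK fell from 9.98 at 0 h to 6.37 at 72 h, and CLE45 and AT2G31540 ended at 6.91 and 9.83.

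The middle against the early window asked what changed in the second day. Most measured mitotic genes were higher, although the largest step lay within the early window, and neither list below passed camera with an estimated correlation (adjusted p = 0.234 for G2 and M phase and 0.807 for mitosis). The 1 measured S phase gene rose 1.65-fold (adjusted p = 0.00393 in limma) but stayed under the log2 cutoff of 1. None of 5 DNA replication or 6 histone genes passed either, although all of their differences were above 0. Less its value at 0 h, the median level of the G2 and M phase list was 0.39 at 18 h. It was 1.91 at 24 h and 2.39 at 30 h, and for the added mitosis list 0.61, 2.15 and 2.64. These are differences of median levels, not median changes of genes. Of the 3 G2 and M phase genes, the middle one was AUR3 at 0 h (6.53). By window means it was AUR2 in the middle window (9.23). All 3 measured members of the G2 and M phase list passed the test, over all genes and over the list alone: the Aurora kinase genes AUR1 (5.03-fold), AUR2 (4.46-fold) and AUR3 (3.2-fold), with adjusted p between 0.000241 and 0.000485. AUR1 went from 7.81 ± 1.03 (SD, n = 4) to 10.14 ± 0.33 (SD, n = 4). In a list of mitotic genes added after the annotation was seen, 12 of 13 rose, with a median log2 difference of 2.17. Of 5 measured procambium and cambium genes, 2 rose, BRL1 by 2.71-fold and AT5G02460, listed as PEAR2, by 2.46-fold (adjusted p = 0.000324 and 0.000373). Of the 5 phloem genes, CLE45 rose 3.32-fold and OPS, a regulator of protophloem differentiation, 2.75-fold, while the sucrose transporter gene SWEET11 fell 2.47-fold. CLE45 stood at a low 3 ± 0.12 (SD, n = 4) in the early window, and with values floored at the 40th percentile its difference turned to -0.38 (adjusted p = 0.0896).

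Photosynthesis genes fell further, 10 of 11 over all genes and over the list alone, with a median log2 difference of -1.91. The Calvin cycle genes PRK, RCA and SBPASE fell 5.18-fold, 4.45-fold and 3.92-fold (adjusted p between 8.7e-05 and 0.00052). Over the settings their log2 differences ranged from -2.80 to -1.70, from -2.46 to -1.48 and from -2.37 to -1.30. The calls held in each setting, but the size of these falls was not settled. SPCH fell 3.13-fold and SAG29 fell 9.34-fold. Among auxin response genes, IAA30 and IAA29 rose 3.26-fold and 2.29-fold, and GH3.3 fell 2.01-fold, a call that ended in 6 of 25 settings: under quantile normalization, on the values as deposited, under centring on named probe sets and without the 18, 42 or 48 h array, with a log2 difference as small as -0.33. AT1G36060, listed as the wound-response regulator WIND3, rose 2.44-fold, and AT5G27120, listed as the nucleolar protein gene NOP58, rose 2.32-fold, the 1 of 4 ribosome biogenesis genes past the test. The call of IAA29 ended without the 6 h array, those of SPCH and SWEET11 on the values as deposited, and that of AT1G36060 with the floor at the 40th percentile.

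The largest rises were those of LCR25 (24.6-fold) and PDF2.1 (12.6-fold), both of which encode defensin-like peptides, AT3G42725 (12.2-fold), AT3G02120 (9.25-fold) and AT5G15510 (8.43-fold), with AT1G32570, AT5G23830 and BGLU15 between 7.47 and 7.95-fold. Most of these varied widely within the early window, with an SD of 2.31 for LCR25, 1.53 for AT3G42725 and 1.57 for BGLU15, but 0.45 for PDF2.1 and 0.39 for AT5G23830. Over the settings the log2 difference ranged from 2.17 to 4.58 for AT3G42725, 1.85 to 4.04 for AT3G02120 and 2.00 to 3.83 for AT5G15510. The largest falls were those of AT5G42530 (10.4-fold), AT1G68570 (9.83-fold), AT1G80130 (9.57-fold), SAG29, ECS1 (9.2-fold) and the cold-regulated gene COR15A (9.12-fold), followed by AT1G70820 and AT5G13140. In all, 561 genes were higher and 912 lower, 38.1% higher. That split follows the scaling. The share higher was 92.3% on the values as deposited and 56.9% with centring on named probe sets, so which direction held more genes was not settled. The median difference over all genes was -0.25.

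The late against the middle window asked what changed in the third day. Of 15 measured members of an added list of genes co-expressed with secondary walls, 12 rose and 0 fell, with a median log2 difference of 1.7 (camera adjusted p = 3e-06, and adjusted p = 0.807 with an estimated correlation). The rise was not the first. Less its value at 0 h, the list's median level was 2.15 at 24 h and 1.10 at 30 h. It was 0.67 at 36 h and 4.09 at 72 h. The drop from 24 to 30 h crosses the break between the array sets, so set and time cannot be told apart there. The middle against the early window crosses that break too. In it 13 of the 15 differences were above 0, with a median of 0.53. Members named after their values were seen were IRX15 and IRX15-L, which act in xylan synthesis, at 3.25-fold and 2.98-fold, and the xylan acetylation genes TBL33 and TBL34 at 3.43-fold and 2.82-fold. Of the 2 measured members of the secondary wall list fixed before the data were examined, 0 passed over all genes and 1 rose adjusted over the list alone, the xylan synthesis gene GUT2, listed as IRX10, with a log2 difference of 1.28 (adjusted p = 0.0852 over all genes). AT1G66810, listed as the wall regulator C3H14, rose 2.62-fold (adjusted p = 0.00134) as the 1 measured xylem regulator. In the phloem list CLE45 rose a further 3.47-fold and SWEET11 fell a further 2.89-fold (adjusted p = 0.000136 and 0.00823). AT1G36060 rose 2.18-fold. RR16, a cytokinin response regulator gene, rose 2.02-fold (adjusted p = 0.0375), a call that ended in 12 of 26 settings, among them quantile normalization, the values as deposited, centring on named probe sets and the leaving out of any single one of the 8 arrays of 30 to 72 h. Of the 11 photosynthesis genes, 0 passed over all genes or over the list alone, although all 11 differences were below 0 with a median of -0.62.

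The largest rises were those of AT2G31540 (12.4-fold), AT1G05770 (11.9-fold), AT5G53600 (11.2-fold), AT5G52270 (11.1-fold) and AT1G11500 (10.4-fold), with AT1G69325, AT3G58380 and AT5G45520 between 9.28 and 10.2-fold. AT2G31540 went from 5.66 ± 0.83 (SD, n = 4) to 9.3 ± 0.55 (SD, n = 4). The largest falls were those of AT3G54400 (4.84-fold), AT3G22060 (4.52-fold), AT3G16670 (4.47-fold), AT3G50400 (4.23-fold), AT5G50915 (3.9-fold), AT3G05936, AT4G14090 and AT3G53980. In all, 429 genes were higher and 161 lower, 72.7% higher. The 8 arrays of 30 to 72 h alone gave 442 and 200. The count lower moved to 78, 74, 106 and 76 without the 30, 36, 66 and 72 h arrays and to 274 without the 48 h array, and the calls of AT3G50400, AT4G14090, AT3G53980 and AT1G36060 each ended without some single array.

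As lists, 9 of 18 tests of the fixed lists passed camera with the preset correlation of 0.01, and 0 passed with an estimated correlation, where 4 had an unadjusted p under 0.05. In the early window against 0 h these were auxin response (adjusted p = 4.53e-05, and adjusted p = 0.172 with an estimated correlation), photosynthesis (0.0014, and adjusted p = 0.426 estimated) and phloem (0.0337, and adjusted p = 0.172 estimated). In the middle against the early window they were photosynthesis (0.000221, and adjusted p = 0.37 estimated), ribosome biogenesis (0.000717, and adjusted p = 0.241 estimated), procambium and cambium (0.00109, and adjusted p = 0.172 estimated), G2 and M phase (0.0014, and adjusted p = 0.234 estimated) and phloem (0.0337, and adjusted p = 0.172 estimated). In the late against the middle window photosynthesis passed (0.000115, and adjusted p = 0.37 estimated). Of the added lists, mitosis passed in the middle against the early window (1.01e-09, and adjusted p = 0.807 estimated) and in the early window against 0 h (0.02, and adjusted p = 0.87 estimated). Secondary wall co-expressed genes passed in the late against the middle window (3e-06, and adjusted p = 0.807 estimated) and in the middle against the early window (0.0102, and adjusted p = 0.87 estimated), so neither list was confined to 1 comparison. Cytosolic and plastid ribosomal protein, plastid-encoded, histone and DNA replication genes each passed in at least 1 comparison too, and 0 added lists passed with an estimated correlation.

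**Figure D3:**
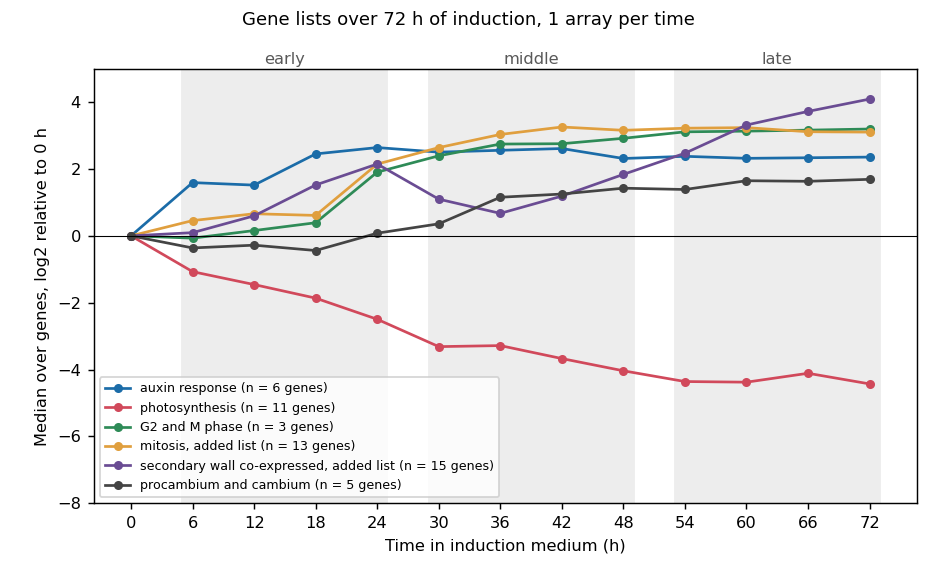
Median log2 level over the genes of a list, less that median at 0 h, against hours in induction medium, 1 array per time. The gene at the median can differ between times, so a value is not the median change of the genes. The auxin response list was higher from 6 h, the mitotic lists stood higher at 24 than at 18 h, the photosynthesis list spanned 4.43 from its highest to its lowest value, and the added secondary wall co-expressed list reached its maximum at 72 h.

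The order of the lists in time was described without a test. It was the time at which a list's median level first crossed the midpoint of its range, in either direction. The auxin response list reached it at 4.97 h and the phloem list at 4.51 h, but without the 0 h array these became 15.61 and 45.57 h. The 45.57 h was a crossing on the way down, from a phloem median of 9.36 at 42 h to 8.90 at 48 h. The photosynthesis list reached it on its way down at 21.33 h, the mitosis list at 21.97 h and the G2 and M phase list at 22.64 h. Their order was not settled: photosynthesis came after mitosis under quantile normalization (22.56 and 22.24 h) and with the mean over members (24.33 and 22.22 h). The procambium and cambium list reached it at 32.01 h, and at 28.43 h with the mean over members. At 0 h and by window means, AT5G02460 was the middle one of its 5 genes throughout. The midpoint from the median is therefore in effect that of 1 gene. Of the 5 genes, 2 passed the test in the middle against the early window. The added list of secondary wall co-expressed genes first crossed it at 23.01 h, but without the 24 h array at 49.96 h.

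Along the whole course, 5091 of 10982 genes followed a smooth curve with a fitted range of at least 1, of which 1856 ended higher and 3235 lower than they began. The fitted peak lay at 0 h in 2591 of them and at 72 h in 956. These splits follow the scaling across the array sets: 36.5% ended higher here, 41.9% under quantile normalization, 49.5% with centring on named probe sets and 75.9% on the values as deposited, where 957 peaked at 0 h. Which direction held more courses was therefore not settled. The largest fitted log2 ranges were those of LCR25 (8.17), AT5G52270 (7.67), AT2G31540 (7.24), AT5G52390 (6.85) and AT3G63050 (6.65), each with an adjusted p of at most 0.00748 with a term for the array sets. With that term 3666 genes were called, 3378 of them in both fits.

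A 24 h rhythm was tested because the seedlings were raised in continuous light. In limma, 9 genes passed, and 1346 had an unadjusted p under 0.05. Among these 9, COR27, a cold- and clock-regulated gene, had the largest log2 amplitude, 1.34, followed by AT1G64500 (0.81), AT1G12600 (0.73), AT2G21130 (0.73) and AT5G62720 (0.68). GI, the 1 measured member of the circadian clock list, had an amplitude of 1.03 and an adjusted p of 0.121. The count was 0 with a term for the array sets, where 1419 genes had an unadjusted p under 0.05. It was 0 or 1 without any single array, except for 36 without the 72 h array.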

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

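The test on the spread of the step from 24 to 30 h, and the requirement that matched lists lie within 0.25 of a list's level, were chosen after the results were seen. The other tests here were written down before.

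Of 45 checks, each of a list's median over the 4 arrays of a window, 1 held an array far from the others. The cutoff gives about 1 in 20 by chance for independent values. The arrays of a window are successive times and the lists share them, so that rate does not apply here. In the early window the mitosis list had a median of 7.95 at 24 h against 6.26 to 6.47 at the other times, a gap of 0.878 of the range. Probe sets with no gene name, which the comparisons leave out, changed too. Of 15214 tested, 1089 were higher and 784 lower in the early window than at 0 h, 1171 higher and 1241 lower in the middle than in the early window, and 235 higher and 120 lower in the late than in the middle window.

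The real grouping gave the most genes in both comparisons of 4 against 4 arrays, but that cannot exclude chance. The arrays are successive times, so any drift along the series favours the real split over mixed ones. Of the 35 splits of the 8 early and middle arrays, 1, the real one, gave as many as 1473 genes, and the highest of the others gave 671, with the 24 and 30 h arrays exchanged. Of the 35 splits of the 8 middle and late arrays, 1, the real one, gave 590 genes, and the highest of the others gave 0. Of 100 orders of the arrays in time, 1, the real one, gave 5091 genes on a smooth course, and the highest other gave 2145. Any drift favours the real order in the same way. Of 100 draws with residuals exchanged around the trend, 3, the real one included, gave as many as the 9 rhythmic genes, and the highest other gave 111. At an unadjusted p, 6 of the 100 draws, the real one included, gave as many as the 1346 genes, so the rhythm count is not clear of chance by that measure.

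The step between the 24 and the 30 h array coincides with the break between the array sets. A difference in scale as the whole cause of the calls is argued against by the arrays of 6 to 24 h, which share a scale. Of the 561 genes called higher, 93% had already moved up from 6 to 24 h, against 35.8% of all genes, and of the 912 called lower 93.3% had moved down, against 64.2%. Offsets particular to single genes stay open. In the smooth course with a term for the array sets, that term passed an adjusted p of 0.05 in limma in 19 of 10982 genes. The sets follow each other in time, so the term cannot fully part an offset from change in time. The SD of the step from 24 to 30 h after quantile normalization was 0.385, between the 0.436 of the step before and the 0.286 of the step after, so such offsets and change in time cannot be told apart.

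The fall of the photosynthesis list might come from compression of bright probe sets between the array sets. Of 10000 random lists matched on mean expression, 0% had a median as low as -1.91, the lowest being -1.09, and under quantile normalization the median was -1.74. That argues against compression as the whole cause for this list. For the plastid-encoded genes 0% of random lists had a median as low as -0.85 either, but these genes were brighter than their matched genes by 0.687, so the lists were not matched and compression and a fall cannot be told apart. Their median was -0.28 under quantile normalization. What caused the fall of the photosynthesis list within the sets was not tested, and the fall was found and examined on the same arrays.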

How the results depend on the processing

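The fits within an array set, the term for the array sets and the centring on named probe sets were chosen after seeing the data; the other settings were planned. No paired analysis was possible because each time point has 1 array. The early window against 0 h gave no value without the 0 h array. The cause of the changes below was not tested, except that filters and windows change how many genes or arrays enter.

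For the middle against the early window, values as deposited gave 1821 genes higher and 151 lower, no filter gave 1697 lower, windows of 6 to 18 and 36 to 48 h gave 1454 lower, and centring on named probe sets 571 lower. For the late against the middle window, windows of 30 to 42 and 60 to 72 h gave 275 lower. For the early window against 0 h, no filter gave 1079 lower, leaving out the lowest 50% gave 299 lower, 6 and 12 h alone gave 394 lower, and the 5 arrays of 0 to 24 h alone gave 287 higher and 157 lower. The smooth course gave 8913 genes with no filter and 3255 with the lowest 50% left out. The rhythm gave 2 genes on values as deposited, 5 with the lowest 50% left out, 5 with the floor at the 40th percentile, 207 with array weights, 1 with a spline trend and 1 at a period of 28 h. It gave 0 without the intensity trend (1345 at an unadjusted p in limma), 0 at a period of 20 h (326), 0 with 0 h (802) and 0 with a term for the array sets (1419). An array-weight fit stopped before it converged, so values with array weights are approximate. The fixed lists gave 0 calls with an estimated correlation, against 9. The ribosome biogenesis list reached its midpoint at 23.28 h under quantile normalization, against 0.02 h, and the secondary wall co-expressed list at 44.67 h with the mean over members. The 0.02 h, like the 0.01 h given below for the same list, was a crossing on the way down. That list's median was 8.325 at 0 h, 7.59 at 12 h, 7.70 at 18 h and 8.47 at 24 h. CLE45 in the middle against the early window turned to -0.38 with the floor at the 40th percentile.

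Leaving out each array gave 503 to 671 genes higher and 740 to 1266 lower in the middle against the early window, 351 to 490 higher and 74 to 274 lower in the late against the middle window, and 622 to 829 higher and 502 to 916 lower in the early window against 0 h, the 916 without the 6 h array. It gave 4536 to 5189 genes on a smooth course and 0 to 36 rhythmic genes. Midpoints ranged from 4.92 to 15.61 h for auxin response, 4.48 to 45.57 h for phloem, 0.01 to 23.29 h for ribosome biogenesis, 21.25 to 49.96 h for the secondary wall co-expressed list, 20.75 to 25.87 h for photosynthesis, 21.65 to 25.02 h for G2 and M phase, 19.81 to 24.01 h for mitosis and 30.1 to 33.59 h for procambium and cambium. The 45.57 h for phloem was a crossing on the way down. Over all settings, 2015 values of named genes kept their side of the threshold and direction, 89 lost the threshold and 1 reversed. Signal over background was not given, so its limit on dim genes is unknown.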

Other observations

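Among the lists added after the annotation was seen, cytosolic ribosomal protein genes held few single genes past the test, 0 of 59 in the early window against 0 h and 1 of 59 in the middle against the early window. Their median log2 difference was -0.40 in the early window against 0 h (camera adjusted p = 0.000381, and adjusted p = 0.87 with an estimated correlation) and 0.34 in the middle against the early window (8.38e-13, and adjusted p = 0.87 estimated). Of 6 plastid ribosomal protein genes, 3 fell in the early window (camera adjusted p = 0.043, and adjusted p = 0.87 estimated) and 5 in the middle window (0.0754, and adjusted p = 0.87 estimated), and of the 2 measured chloroplast NDH complex genes, both fell in the middle window, with a median of -2.10. Of 63 plastid-encoded genes, 12 fell in the middle window (2.65e-18, and adjusted p = 0.87 estimated), 1 in the early window (0.0167, and adjusted p = 0.893 estimated) and 0 in the late window (1.35e-08, and adjusted p = 0.87 estimated). The median difference in the middle against the early window was 0.31 for 6 histone genes (0.0436, and adjusted p = 0.87 estimated) and 0.49 for 5 DNA replication genes (0.0181, and adjusted p = 0.87 estimated), with 0 genes of either past the test. In the late against the middle window the histone median was 0.42 (0.0291, and adjusted p = 0.807 estimated), again with 0 past the test. In the middle against the early window the median was -0.59 for 3 SAUR genes and 0.18 for 4 further phloem genes, with 0 past the test, and in the late against the middle window -0.12 and -0.11, with 1 gene of each list lower.

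A group of 55 genes was higher in the early window than at 0 h and lower in the late than in the middle window. Independent lists of these sizes would share 10.1. The differences share no array, but the calls share a spread fitted over all 13 arrays. A gene with a small spread is more easily called in both comparisons, so 10.1 is not a valid measure of chance. Higher in both comparisons were 41 genes, against 27 for independent lists. Lower and then higher were 11 against 23.6, and lower in both were 9 against 8.8. Genes are not independent replicates, so no p is given. Chosen after their values were seen, DFR, which encodes the dihydroflavonol reductase of anthocyanin synthesis, went from 4.87 at 0 h to a mean of 9.32 early, 8.49 in the middle and 6.23 late. UF3GT, an anthocyanin glycosyltransferase gene, went from 3.91 to 6.54, 5.57 and 3.73. SWEET4 went from 4.72 to 9.75, 7.68 and 6. APL3, a starch synthesis gene, went from 6.19 to 10.23, 8.56 and 7.51.

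Genes called higher in the late window seemed, from the identifiers of those with the largest rises, to include neighbours in the genome. The hypothesis that neighbours rise together was written down after that impression and before any pair was counted. Among 4700 pairs of neighbouring tested genes in the TAIR10.1 order, 25 were both called higher in the late than in the middle window. Of 10000 random sets matched on mean expression the median was 7 and the highest 20. Runs of this kind were AT5G04680, AT5G04690 and AT5G04700, AT5G45520, AT5G45530 and AT5G45540, and AT1G23510, AT1G23520 and AT1G23530. Further runs were MYR2, AT3G04040 and AT3G04050, and AT4G16000, AT4G16008 and AT4G16015. CLE45 and its neighbour AT1G69580 were another pair. Shared regulation is a candidate explanation, but neighbours are often copies of each other, and probe sets that read both copies could give the same count. Probe sequences were not used here, so that was not tested. The excess was not particular to the late rise. By the rule of exceeding all but 1% of the random sets, 52 pairs called lower in the middle window (99th percentile 45) and 32 called higher in the early window (99th percentile 30) passed too. The 19 pairs called higher in the middle window, 2 called lower in the late window and 20 called lower in the early window did not.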
